A study of Mus musculus with 2 samples.

How the data were processed

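The samples were 2 libraries of tumour-infiltrating T cells from BALB/c mice, 4 to 6 weeks old, with subcutaneous EMT6 tumours that were randomised at a volume of 80 to 150 mm3, per the labels. The treated group received 2 cycles of mSTAR1302 into the peritoneum at 1 dose per week, and the control group received vehicle. Per the labels' protocols, tumours were digested with collagenase and DNase, CD4+ and CD8+ cells were isolated with magnetic beads, 3' gene expression libraries were made on a 10x Genomics Chromium instrument and sequenced on a NovaSeq to at least 50000 reads per cell. The groups were taken from the labels, with 1 library in each.

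The deposited values are whole-number UMI counts per gene and barcode that the authors made with Cell Ranger. The matrix headers name version 4 and the submitters' processing notes name version 6.0.1, so the version behind these counts is uncertain. The notes also name the mm10 genome, FastQC, MultiQC 1.9 and Seurat, and the annotation release is not given in the sources used here. The matrices were unfiltered, with 1728776 listed barcodes for mSTAR1302 and 1910622 for vehicle, 32285 genes, and totals of 96486469 and 110026997 UMIs. No cell annotation by the authors was used here. Gene identifiers were matched to GENCODE M21 on GRCm38, the same assembly as mm10, and 32158 of 32285 had an entry there. Positions come from that annotation, and 78 symbols were shared by several identifiers.

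A barcode was kept as a cell with at least 1000 UMIs (11476 and 9621 barcodes), at least 500 genes (11027 and 9319 of them) and at most 10% mitochondrial UMIs (9155 and 7615). The mitochondrial limit removed 1872 barcodes (17.0%) and 1704 (18.3%). Doublets were called per library with Scrublet in scanpy 1.11.5 at an expected rate of 0.8% per 1000 cells. Scrublet marked 2 of 9155 and 1 of 7615 cells against 7.32% and 6.09% expected, so the caller is taken not to have worked, and doublets remain in the data. 9153 and 7614 cells were kept, with 69415171 and 83838909 UMIs. Counts were scaled to 10000 per cell and log transformed. The 2000 most variable genes, without T cell receptor, mitochondrial and ribosomal protein genes, gave 30 principal components, a shared neighbour graph of 20 neighbours and Leiden clusters at resolution 1.0 with seed 1 (leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0). No integration was applied, so a cluster mostly of 1 library may be that library and not a type. The other tools were Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

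Clusters were named from markers fixed before the data were examined. A cluster was T-like with at least 4 of the markers Cd3d, Cd3e, Cd3g, Trac, Trbc1, Trbc2, Cd2 and Lat each in at least 50% of its cells. It took the name of another class with at least 3 of that class's markers at 4-fold or more over the remaining cells and in at least 20% of cells. Marker lists covered gamma delta T cells, NK cells, B cells, plasma cells, macrophages and monocytes, neutrophils, dendritic cells, mast cells and basophils, the EMT6 tumour, fibroblasts, endothelium, erythroid cells and platelets. The thresholds for naming, unlike the markers, were set after the data were seen. A cluster with a median under 1 part in 3 of its library's UMIs and without markers of its name among its top 10 genes stayed unnamed, and so did a cluster with enough T cell markers but too few of another class if its top 10 genes held a marker of another class that stands in no gene list and held no T cell marker. The latter left out cluster 19, with 52 cells, where 7 T cell markers passed but Ncr1, an NK cell marker, was among the top genes. Of 23 clusters 14 were T-like and 3 stayed unnamed. Genes that lead some T-like clusters (Gzma, Ly6c2 and Ccr7) also stand in the NK, macrophage and dendritic cell marker lists, so the T-like class was used only to select cells, its size was not compared between groups, and the gates were also read on all kept cells. An unnamed cluster of low UMI counts held 449 vehicle and 88 mSTAR1302 cells, and 45.4% of its cells had a Foxp3 UMI. Cluster 15, with 230 cells, 207 of them vehicle cells, had a median of 17160.0 UMIs, with Cd8a in 97.0%, Cd4 in 67.4% and Foxp3 in 86.5% of cells, a profile that droplets with several cells would also give.

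Within T-like clusters cells were gated as CD8, as CD4 without a Foxp3 UMI or as CD4 with at least 1 Foxp3 UMI. For expression, UMIs were summed over the cells of a gate and library and divided by their total to give CPM, and log2 ratios of mSTAR1302 over vehicle used a pseudocount of 1 CPM. The summed UMIs were 48030010 and 26262370 in CD8 cells, 5207289 and 3953614 in CD4 cells without Foxp3, and 1230862 and 13981953 in CD4 cells with Foxp3. Cells are not replicates and each group is 1 library, so no test was made. CPM values carry exact Poisson intervals, ratios exact conditional binomial intervals, shares exact Clopper-Pearson intervals, and differences of shares a hybrid interval built from the exact bounds, all at 95% and for counting error only. Against a count of 0 a ratio was taken to the floor of 3 counts. Shares of cells with a UMI of a gene were also read after thinning each cell to 3000 UMIs, leaving out shallower cells. Free RNA was profiled from barcodes of 50 to 400 UMIs, and the amount subtracted per cell was the mean UMIs of such a barcode, 3.06% and 1.99% of the UMIs of CD8 gated cells. The most that free RNA can hold of these UMIs was read, after the data were seen, as the CPM of 11 macrophage markers outside the gene lists in CD8 gated cells over their CPM in free RNA, 7.445% and 4.06%, and the share a gene would need as its CPM difference over its CPM in free RNA of the library where it is higher.

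The rule for named genes was fixed before the data were examined. Among genes with at least 20 CPM in either library and at least 50 UMIs over both, without T cell receptor and immunoglobulin segments, mitochondrial and ribosomal protein genes, the 12 with the largest log2 ratio in each direction were named in CD8 cells and in CD4 cells without Foxp3, and 6 in CD4 cells with Foxp3. Members of the gene lists may be named as examples of their list, and every Trbv gene may be named. The 15 gene lists, fixed at the same time, were cytotoxic effector, inhibitory receptors and exhaustion, naive and memory, interleukin-2 and STAT5 response, proliferation, regulatory T cell, T cell receptor signalling and activation, type I and II interferon response, T helper subsets, chemokines with homing and residence, glycolysis, nuclear oxidative phosphorylation, heat shock and dissociation, apoptosis and stress, and RNA quality. A member counted as measured with at least 10 UMIs over both libraries. A list's median has an interval from 1000 Poisson resamples and a percentile among 10000 random lists of the same size matched on mean expression in 50 bins. The percentile describes these 2 libraries and is no test.

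The procedure was tested on simulated counts drawn for the measured genes of each population, with 200 genes changed. The counts were independent Poisson draws around the pooled rate of each gene, without variation between cells or mice or dependence between genes. Interval coverage near 95% thus follows from the setting. The simulation checks the calculation and does not show that the intervals or percentiles hold for real cells. In the CD8 step of 4916 genes all 4-fold genes were found at least 2-fold apart, none of the 4716 unchanged genes was, and 95.7% of the intervals of unchanged genes held the true ratio. Of genes simulated exactly 2-fold higher 8.0% and of those 2-fold lower 50.0% passed the 2-fold limit. In the CD4 step without Foxp3 (4902 genes) and in the step with Foxp3 (5408 genes) all 4-fold genes were found as well. Lists of 20 unchanged genes fell within the central 95% of random lists in 97.0%, 99.5% and 96.0% of 200 draws for the 3 populations.

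Alternatives chosen beforehand were minimums of 500 UMIs with 300 genes and of 2000 UMIs with 1000 genes, mitochondrial limits of 5% and 20%, doublets kept, a gate at 2 UMIs, gates on all kept cells, thinning to 1000 UMIs before gating, scaling by median ratios, a total without T cell receptor, mitochondrial and ribosomal protein genes, the mean over cells, free RNA subtracted, a pseudocount of 5 CPM, minimums of 50 CPM or none for counted genes and of 10 CPM for list members, and Trbv genes of at least 20 UMIs. Alternatives added after the data were seen were removal of the highest doublet scores, whole clusters in place of gates, the CD8 gate without cells that hold a Foxp3 UMI, Foxp3 thinned to 3000 UMIs with the gate at full depth, the CD4 gate without clusters in which at least 50% of cells held a Foxp3 UMI, and the CD4 gate without cluster 14, the T-like cluster with both Tcf7 and Lef1 among its top 10 genes. Cells with both or neither of the Cd4 and Cd8 transcripts and cells outside T-like clusters entered no expression comparison. Full-length receptor sequences were not analysed here, and the values of some list members are not reported here.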

Results

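Tumour-infiltrating T cells were profiled by droplet single-cell RNA sequencing from BALB/c mice that carried subcutaneous EMT6 tumours, a transplantable line of mouse mammary carcinoma. The mice received mSTAR1302 or vehicle. mSTAR1302 is described by its makers as an antibody to the mouse T cell receptor chains Vβ13-2 and Vβ13-3 fused to interleukin-2, a growth factor for T cells. CD4+ and CD8+ cells were enriched from digested tumours with magnetic beads before the droplets were made. Each group was 1 library, so the differences below have no replicate check, no test between groups was made, and every 95% interval covers counting error only. The number of mice behind each library is not given in the sources used here. The mSTAR1302 library held 96486469 unique molecular identifiers (UMIs) and the vehicle library 110026997. After filtering, 9153 cells with a median of 6260.0 UMIs and 1900.0 genes were kept from the mSTAR1302 library, and 7614 cells with a median of 8447.5 UMIs and 2491.5 genes from the vehicle library. Mitochondrial transcripts took a median of 3.68% and 3.02% of a cell's UMIs. T-like clusters held 8647 and 6286 of these cells. Within them, cells were gated on single transcripts, as CD8 (at least 1 UMI of Cd8a or Cd8b1 and none of Cd4) or CD4 (at least 1 UMI of Cd4 and none of Cd8a or Cd8b1).

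The first comparison asked how the makeup of the tumour T cells differed between treated and control mice. CD8 T cells, the cytotoxic lineage, took a larger share of the gated T cells in the mSTAR1302 library, and regulatory T cells, the suppressive CD4 lineage that depends on the transcription factor Foxp3, took a smaller share of the CD4 cells. CD8 cells made up 86.9% of the 7171 gated cells in the mSTAR1302 library (exact Clopper-Pearson interval 86.1 to 87.7%) and 55.4% of 4284 in the vehicle library (53.9 to 56.9%), a difference of 31.56 percentage points (29.9 to 33.3). A Foxp3 UMI was found in 15.3% of the 937 CD4 gated cells of the mSTAR1302 library (13.02 to 17.7%) and in 69.4% of 1912 in the vehicle library (67.3 to 71.5%), a difference of -54.14 points (-57.2 to -50.9). CD4 cells without a Foxp3 UMI made up 11.1% and 13.7% of the gated cells, so most of the difference in the CD4 compartment lay in the Foxp3 cells, which were 1.99% and 31.0% of all gated cells. The ratio of CD8 to CD4 cells was 6.65 with mSTAR1302 and 1.24 with vehicle, and that of CD8 cells to CD4 cells with Foxp3 was 43.6 and 1.79. Both lineages were isolated with magnetic beads, so the CD8 share and these ratios can also depend on how many cells of each were recovered. Bead recovery was not measured here.

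Single-cell shares of this kind depend on depth and on free RNA, and the vehicle cells were the deeper ones. CD8 gated cells had median UMI counts of 6610.5 and 9844.5 in the mSTAR1302 and vehicle libraries, and CD4 gated cells 6099.0 and 7552.5. For comparison, a Foxp3 UMI was found in 2.98% and 15.7% of CD8 gated cells and in 0.707% and 2.998% of near-empty droplets. In macrophage-like cells, which were deeper (median 9366.0 and 26770.0 UMIs), it was found in 2.41% and 18.2%. After thinning to 3000 UMIs the shares were 1.63% and 8.30% of CD8 gated cells and 0.0% and 1.92% of macrophage-like cells. At equal depth the CD8 gate of the vehicle library thus held Foxp3 more often than macrophage-like cells did. With every cell thinned to 1000 UMIs before gating, the CD8 share was 92.3% against 74.8%, a difference of 17.48 points (15.7 to 19.3), and the Foxp3 share of CD4 cells was 7.50% of 400 cells against 27.4% of 707, a difference of -19.94 points (-24.1 to -15.5). With the gate at full depth and Foxp3 read after thinning to 3000 UMIs, an alternative chosen after the data were seen, the shares were 11.8% of 821 cells and 51.9% of 1790, a difference of -40.08 points (-43.3 to -36.7), with 116 and 122 shallower cells left out. Cells with both Cd4 and Cd8 UMIs, which no gate took, were 9.62% and 18.7% of T-like cells. Cells with neither were 7.45% and 13.2%. The transcripts that set the gates also stood in free RNA. Near-empty droplets held Cd8a in 7.36% and 5.16%, Cd8b1 in 9.67% and 5.20% and Cd4 in 1.18% and 2.18%, so free RNA could add to the CD8 difference. How many cells changed gate through free RNA was not tested. The beads can set how many cells of other types remained, among which macrophage-like cells were 0.907% and 3.03% of all kept cells, dendritic cell-like cells 0.229% and 3.90%, fibroblast-like cells 0.0765% and 1.22%, endothelial-like cells 0.0765% and 0.539% and EMT6 tumour-like cells 0.219% and 0.762%. Clusters left unnamed held 4.02% and 7.99%.

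**Figure D1:**
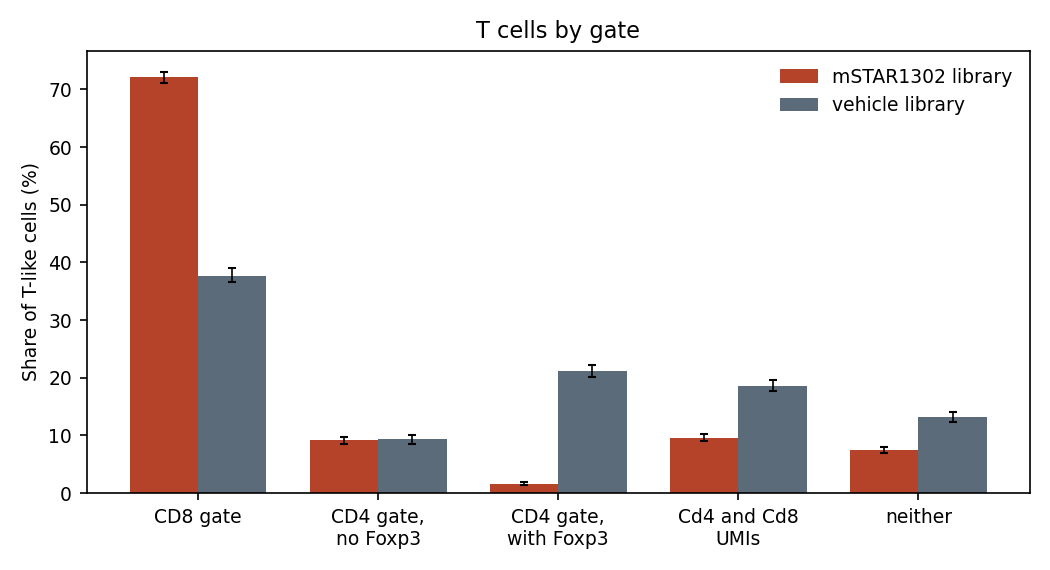
Share of T-like cells in each gate, in percent of T-like cells, for the mSTAR1302 and vehicle libraries. Bars are shares with exact 95% intervals for counting error, and CD8 gated cells were 72.1% of T-like cells with mSTAR1302 and 37.7% with vehicle, while CD4 gated cells with a Foxp3 UMI were 1.65% and 21.1%.

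The second comparison asked whether T cells that use the receptor chains bound by mSTAR1302 were more common in treated tumours. In CD8 cells they were. Trbv13-3 and Trbv13-2, the gene segments that encode these Vβ chains, took 43.6% of the 2170 Trbv UMIs of CD8 gated cells in the mSTAR1302 library (41.5 to 45.8%) and 15.2% of 857 in the vehicle library (12.8 to 17.7%), a difference of 28.47 points (25.2 to 31.6). Trbv13-3 alone took 29.5% against 5.95%, and Trbv13-2 14.1% against 9.22%. The neighbouring segment Trbv12-2 was also at a higher share, 18.3% against 9.22%, while Trbv19 took 7.24% against 16.7%, Trbv5 2.40% against 13.3%, Trbv2 8.71% against 11.7% and Trbv13-1 2.03% against 3.97%. Of the CD8 gated cells with any Trbv UMI, 801 of 1595 held a Trbv13-2 or Trbv13-3 UMI in the mSTAR1302 library (50.2%) and 100 of 597 in the vehicle library (16.8%).

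In CD4 cells the shares lay close together. Trbv13-2 and Trbv13-3 took 13.2% of 302 Trbv UMIs in CD4 gated cells of the mSTAR1302 library and 11.3% of 594 in the vehicle library, a difference of 1.97 points whose interval held 0 (-2.62 to 6.95). In CD4 cells without Foxp3 the difference was -0.353 points (-6.98 to 5.88). In CD4 cells with Foxp3 the shares were 23.8% of 42 UMIs and 11.0% of 409, a difference of 12.8 points (0.556 to 28.7) that rests on 10 UMIs. A Trbv transcript was caught in a minority of cells, so these shares describe UMIs and not clones. Trbv13-1, Trbv13-2 and Trbv13-3 have similar sequences, and the counting could divide reads between them. With the 3 segments pooled the CD8 shares were 45.7% and 19.1%, a difference of 26.53 points (23.0 to 29.9). Free RNA carried the same contrast, since the 2 segments took 33.5% of Trbv UMIs in near-empty droplets of the mSTAR1302 library and 10.9% in those of the vehicle library. In the mm10 assembly (GRCm38) the segments lie on the plus strand of chromosome 6, Trbv13-1 at 41116007 to 41116468, Trbv12-2 at 41118851 to 41119364, Trbv13-2 (ENSMUSG00000076469) at 41121396 to 41121832 and Trbv13-3 (ENSMUSG00000076470) at 41130147 to 41130585.

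**Figure D2:**
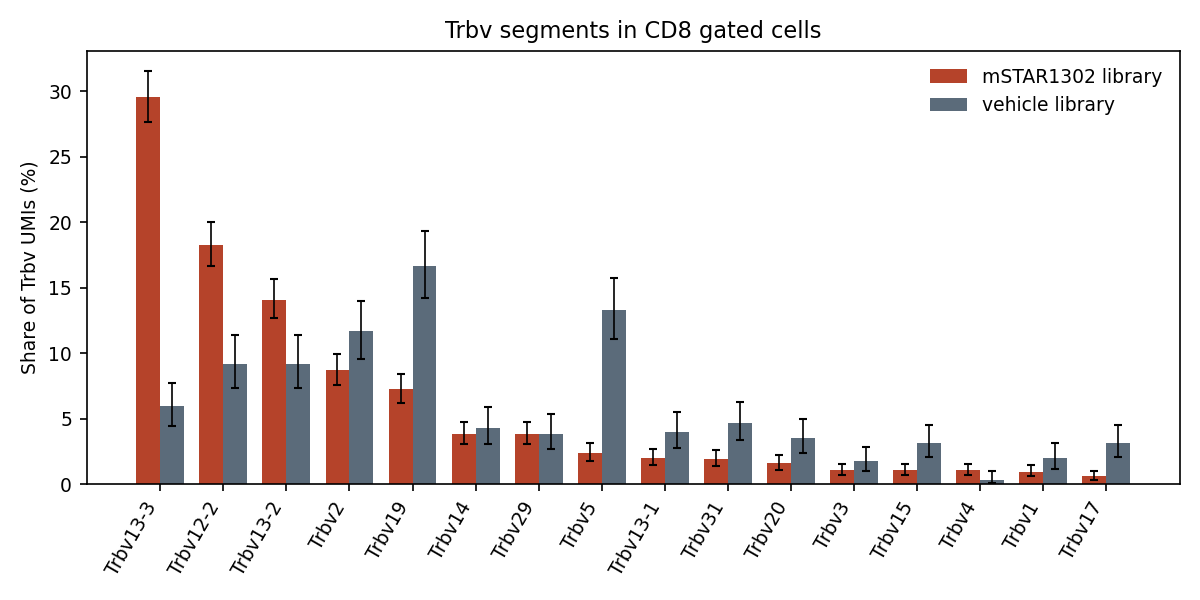
Share of all Trbv UMIs taken by each Trbv segment in CD8 gated cells, in percent, for the mSTAR1302 and vehicle libraries. Bars carry exact 95% intervals for counting error, and Trbv13-3 stands at 29.5% against 5.95%.

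The third comparison asked how the expression state of the CD8 cells differed. CD8 cells of the mSTAR1302 library held more transcripts of the granzymes Gzma, Gzmb and Gzmk, which are the proteases of cytotoxic granules, more of interferon-response genes, and fewer of the exhaustion genes Pdcd1 and Tox. The granzymes Gzmd, Gzme and Gzmf went the other way, 1.501-fold, 1.63-fold and 1.94-fold lower. Gzma stood at 1194.1 CPM (its UMIs summed over the gate and scaled to the gate's UMI total) against 68.7, 17.4-fold higher (16.6 to 18.2), and Gzmb at 1398.1 against 400.4 CPM, 3.49-fold higher (3.42 to 3.56). Pdcd1, the inhibitory receptor PD-1, stood at 107 against 243 CPM and was 2.27-fold lower, and Tox, a transcription factor of exhausted T cells, was 4.20-fold lower. Among 5356 genes with at least 20 CPM in either library, 54 were at least 2-fold higher and 186 at least 2-fold lower in the mSTAR1302 library. The median over these genes was -0.13 on the log2 scale, so a list is placed below by its percentile among 10000 random lists of matched expression. Scaling by median ratios instead moved that median to -0.01 and gave 69 higher and 138 lower genes, 33.3% higher in place of 22.5%. The cluster with the largest part of the gate differed between the libraries, cluster 0 with 47.9% of it under mSTAR1302 and 4.51% under vehicle, and cluster 1 with 13.4% and 60.2%.

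The 12 genes with the largest ratios upward were Gzma, Il13, Esm1, Plac8, Emilin2, Klf3, Ly6c1, Gzmk, Lef1, Ly6c2, Crim1 and Gzmb. Il13, a type 2 cytokine, was 9.45-fold higher, at 42.1 against 4.46 CPM. That level is close to the 42.3 CPM of Il13 in free RNA of the mSTAR1302 library (1.46 CPM with vehicle), and an Il13 UMI was found in 3.61% of CD8 gated cells against 1.01%, and in 2.08% against 0.439% after thinning. To make the Il13 difference, free RNA would have to hold 89.0% of the UMIs of these cells, where macrophage markers allow at most 7.86%, a bound read after the data were seen. Esm1, a secreted proteoglycan, was 7.99-fold and Plac8 5.32-fold higher. Klf3, a zinc finger transcription factor, was 4.83-fold higher and Lef1, a transcription factor of naive and memory T cells, 3.71-fold. Gzmk was 4.56-fold higher (4.15 to 5.01). The 12 with the largest ratios downward were Dapl1, Igfbp7, Bdh2, Cd81, Slc17a6, Penk, Klrg1, Bmyc, Xcl1, Creb3l2, Areg and Sema4c. Dapl1 was 11.6-fold lower (10.4 to 12.9) and Cd81, a tetraspanin, 7.47-fold lower. Penk, the precursor of enkephalins, was 6.45-fold lower. Xcl1, a chemokine that attracts cross-presenting dendritic cells, stood at 163 against 859 CPM, 5.26-fold lower (5.13 to 5.40), and Areg, a growth factor of the epidermal growth factor family, at 53.0 against 264.5 CPM. Gzma is read by droplets without a cell as well. A Gzma UMI was found in 65.1% of CD8 gated cells against 7.72%, in 18.8% of near-empty droplets against 0.367%, and, after thinning to 3000 UMIs, in 54.9% of CD8 gated cells against 4.96%. Pdcd1 was found in 27.5% and 66.5% of CD8 gated cells, and in 18.1% and 40.05% after thinning, against 2.41% and 13.9% of macrophage-like cells without thinning. In mm10, Gzma (ENSMUSG00000023132) lies on the minus strand of chromosome 13 at 113093825 to 113100981, Gzmb on the minus strand of chromosome 14 at 56258838 to 56262260, and Pdcd1 (ENSMUSG00000026285) on the minus strand of chromosome 1 at 94038305 to 94052553.

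**Figure D3:**
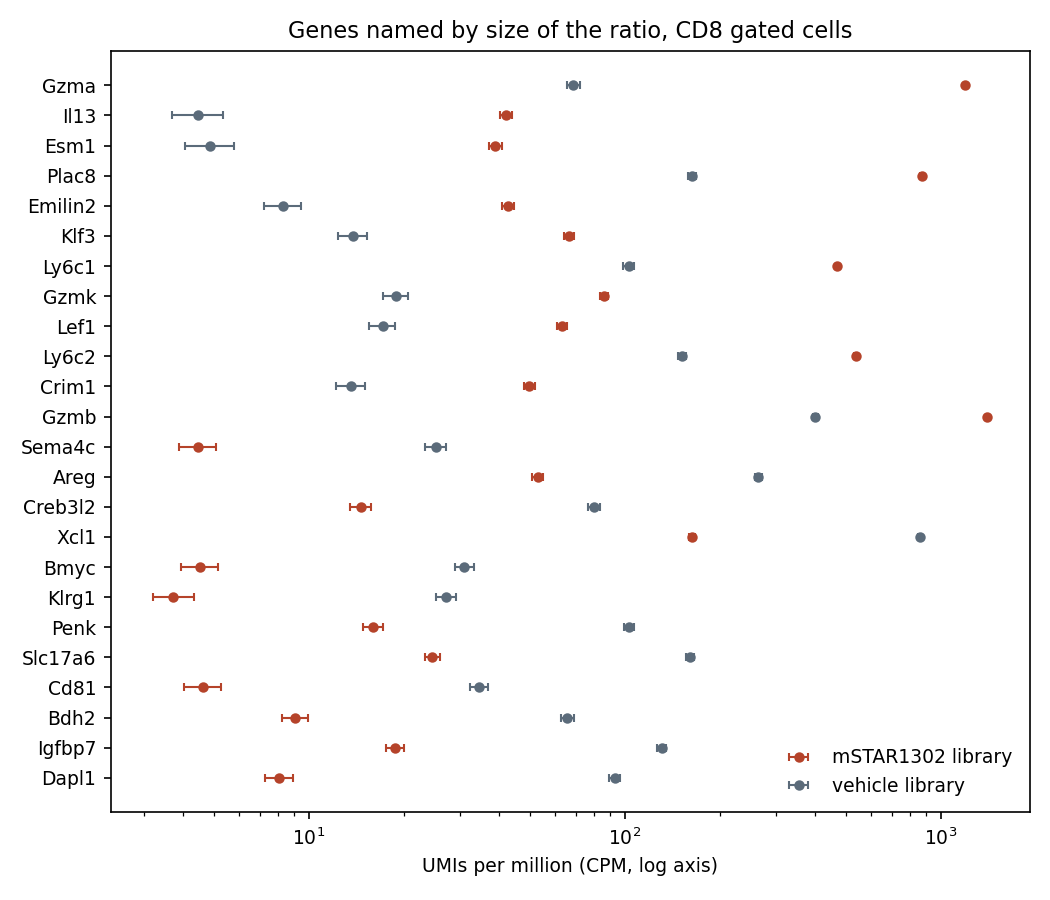
CPM on a log axis of the 24 genes named by size in CD8 gated cells of the mSTAR1302 and vehicle libraries. Error bars are exact 95% Poisson intervals for counting error, and the upper 12 genes were higher and the lower 12 lower in the mSTAR1302 library.

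By gene list, the cytotoxic effector genes of CD8 cells split. Of 26 measured members, 4 were at least 2-fold higher (Gzma, Gzmb, Gzmk and the chemokine Ccl5), 4 at least 2-fold lower (Cst7, Klrg1, Zeb2 and Cx3cr1, the last 3.77-fold) and 18 lay between, among them the pore-forming protein Prf1, 1.40-fold lower. The median log2 ratio was -0.20 (-0.31 to -0.16), at percentile 2.24, and ranged from -0.38 to -0.08 over 16 alternatives. Of 23 members of the inhibitory receptor and exhaustion list, none was 2-fold higher and 6 were 2-fold lower, namely Pdcd1, Tox, Cd200, Nr4a2, Rgs16 and Ikzf2, with a median of -0.69 (-0.72 to -0.64) below all the random lists. Havcr2, the inhibitory receptor TIM-3, lay on the other side, 1.67-fold higher. Without cells that held a Foxp3 UMI, an alternative chosen after the data were seen, 1 member of this list was at least 2-fold higher and 6 at least 2-fold lower. The T cell receptor signalling list had a median of -0.42 (-0.46 to -0.39), also below all the random lists, with Tnfrsf4 2.23-fold lower and Rel, an NF-kappaB subunit, 1.86-fold lower. Heat shock and dissociation genes, which share Fos, Jun and Nr4a1 with that list, had a median of -0.26 (-0.30 to -0.21, percentile 0.17). Interferon-response genes were higher as a group, 30 of 33 above 0 with a median of 0.57 (0.54 to 0.62) above all the random lists, and 5 were at least 2-fold higher, among them Oasl1 (4.12-fold), Gbp2 (2.20-fold) and Rtp4 (2.11-fold).

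The interleukin-2 and STAT5 list had a small positive median in CD8 cells, 0.08 (0.02 to 0.12, percentile 99.9), and a mean of the opposite sign, -0.08. Gzmb was its 1 member at least 2-fold higher, Xcl1 and Tnfrsf4 were at least 2-fold lower, and Il2ra, the alpha chain of the interleukin-2 receptor, was 1.18-fold higher. Its median turned to -0.02 when cells were weighted equally in place of UMIs and was 0.19 with median-ratio scaling. The naive and memory list had a median of 0.06 (-0.0048 to 0.13, percentile 99.55), with Lef1, Klf3, Ly6c1 and Ly6c2 at least 2-fold higher and the lymph node homing receptor Ccr7 (4.54-fold), Bach2 (2.91-fold), Dapl1 and Igfbp4 at least 2-fold lower. This median reached 0.29 with members of at least 10 CPM only. Chemokine and homing genes had a median of 0.26 (0.23 to 0.32) and a mean of -0.16, with 3 members at least 2-fold higher, among them Ccl5 (2.47-fold) and Ccr2 (2.24-fold), and 8 at least 2-fold lower, including Itgae, the residence integrin CD103 (4.27-fold). The regulatory T cell list had the lowest median, -1.19 (-1.25 to -1.10), with 15 of 25 members at least 2-fold lower. The CD8 gate of the vehicle library held more cells with a Foxp3 UMI, as given above, and without such cells, an alternative chosen after the data were seen, the median was -0.78 and 10 of 24 members were at least 2-fold lower. The T helper list had a median of -0.06 (-0.16 to 0.11) and a mean of 0.04, with Il13 and Il17a higher and Il17f and Ccr6 lower.

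Proliferation genes lay close together in the 2 libraries in CD8 cells. Their median was 0.11 (0.07 to 0.14, above all the random lists), with 1 of 39 members past 2-fold, Cenpa, 2.27-fold lower. It was 0.29 without cells that held a Foxp3 UMI and -0.05 when all filtered cells were gated without clusters. Mki67, a marker of dividing cells, was found in 11.8% of CD8 gated cells with mSTAR1302 and 11.1% with vehicle after thinning to 3000 UMIs, a difference of 0.656 points whose interval held 0 (-0.943 to 2.19), with 659 and 95 shallower cells left out. Without thinning the shares were 17.3% and 21.4%. The difference was 2.06 points (0.412 to 3.62) without cells that held a Foxp3 UMI and 1.61 points (0.0757 to 3.08) with whole clusters in place of the gate, both chosen after the data were seen. As a measure of free RNA, Mki67 was found in 1.34% and 2.26% of near-empty droplets, and macrophage-like cells, which can divide, held it in 9.09% and 11.1% after thinning. Of the remaining lists in CD8 cells, glycolysis had a median of 0.06 (0.03 to 0.08), nuclear genes of oxidative phosphorylation 0.04 (0.03 to 0.06) and apoptosis and stress genes 0.11 (-0.01 to 0.17), with the cell cycle inhibitor Cdkn1a 2.20-fold higher. RNA quality genes had a median of 0.16 (0.15 to 0.17). Markers of other cell types were lower in the CD8 gate of the mSTAR1302 library, with medians of -0.69 for macrophages and monocytes, -0.95 for dendritic cells, -0.48 for the EMT6 tumour and -1.285 for fibroblasts. Medians were -0.42 for gamma delta T cells, -0.41 for endothelium, 0.30 for B cells and -0.00495 for neutrophils, and -0.25 for NK cells, whose mean of 0.45 carries Gzma. Plasma cell, mast cell, erythroid and platelet markers had fewer than 3 measured members.

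**Figure D4:**
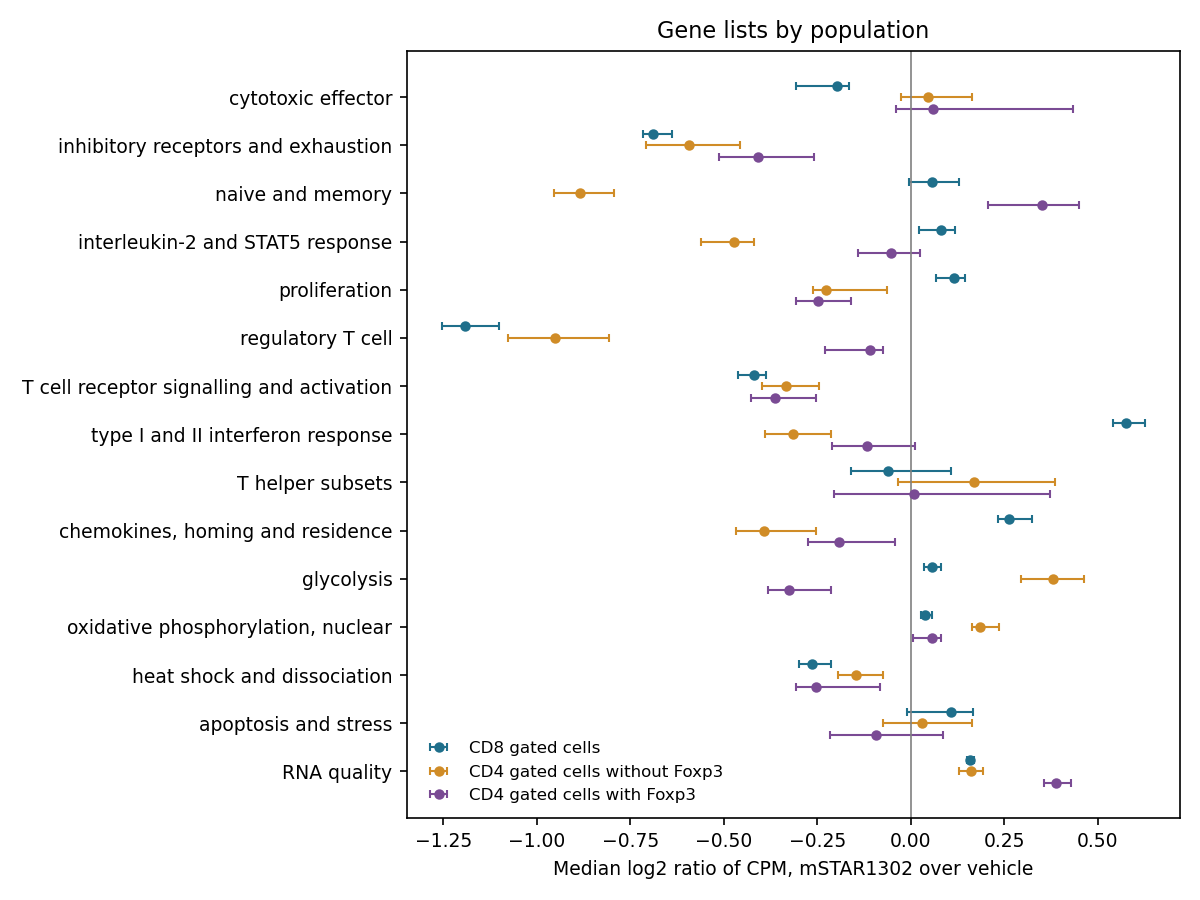
Median log2 ratio, mSTAR1302 over vehicle, of the 15 gene lists in CD8 gated cells, CD4 gated cells without Foxp3 and CD4 gated cells with Foxp3. Bars are 95% intervals from resampled counts and cover counting error only, and the interferon list stood at 0.57 in CD8 cells and -0.31 in CD4 cells without Foxp3.

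The fourth comparison took the CD4 cells without a Foxp3 UMI, 794 cells with mSTAR1302 and 585 with vehicle. These cells held more transcripts of the cytokine genes Il13, Il3 and Il2 and of the interferon-induced transmembrane genes Ifitm1, Ifitm2 and Ifitm3 in the mSTAR1302 library, and fewer of naive and memory genes, where the vehicle cells also held more of a naive-like cluster. Il13 (ENSMUSG00000020383, minus strand of chromosome 11 at 53631324 to 53634702) stood at 148.8 against 6.58 CPM, 22.6-fold higher (15.3 to 34.9), and Il2, the T cell growth factor, at 42.4 against 5.57 CPM, 7.63-fold higher (4.91 to 12.4). The Il2 ratio rests on few cells, since an Il2 UMI was found in 5.16% of cells against 2.91%, and after thinning to 3000 UMIs in 2.47% (1.45 to 3.93%) against 1.53% (0.661 to 2.99%). Il3, a cytokine that acts on blood progenitors, had 213 UMIs against 1, a ratio of 162 with a counting interval of 28.7 to 6417. Its 40.9 CPM lay below the 50.5 CPM of Il3 in free RNA of the mSTAR1302 library. The share of cells with an Il3 UMI was not read, and the interval does not allow for many UMIs in few cells. The bound on free RNA was read in CD8 gated cells only. Ifitm3 stood at 1608.9 against 179.8 CPM (8.95-fold, 8.29 to 9.67), with Ifitm1 6.38-fold and Ifitm2 4.675-fold higher. The other genes among the 12 largest upward were Lgals7 (6.55-fold), Tnp2, the chemokine Ccl1 (4.70-fold), Gzma (4.90-fold), Ly6c1 and Il12rb2, a chain of the interleukin-12 receptor (4.17-fold). Free RNA of the mSTAR1302 library also held more Gzma (925 against 17.6 CPM), Il13 (42.3 against 1.46 CPM), Il3 (50.5 against 6.04 CPM) and Il2 (41.95 against 9.43 CPM). After thinning, Gzma was found in 14.2% of these cells and 13.6% of macrophage-like cells of the mSTAR1302 library, so its level here is not above background. Il13 was found in 7.12% of these cells against 0.763% after thinning, 10.3% against 1.54% before it, and in 0.955% of near-empty droplets against 0.0307%. Among 5402 genes with at least 20 CPM, 48 were at least 2-fold higher and 203 at least 2-fold lower, with a median of -0.20. Median-ratio scaling moved that median to -0.02 and the counts to 63 and 129, or 32.8% higher in place of 19.1%.

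Of the 12 largest downward, 1810009J06Rik had 0 UMIs against 82 and was at least 36.0-fold lower, taking 3 counts as the floor of the library. Pcsk1, a prohormone convertase, had 3 UMIs against 90, a ratio of 39.5 (13.1 to 195) toward vehicle. Itgb8, an integrin that activates TGF-beta, was 35.8-fold lower, Igfbp4 18.9-fold (12.1 to 30.95), Klrg1 17.2-fold and Xcl1 8.29-fold. The rest were Ltf, Ncmap, Trf, Sdc4, Dapl1 and Bmyc. The gate did not hold like cells in both libraries. Cluster 3 held 87.8% of it with mSTAR1302 and 48.7% with vehicle, and the vehicle gate also drew 23.6% from cluster 2, where at least 50% of cells held a Foxp3 UMI, and 12.65% from cluster 14 (1.13% with mSTAR1302), a naive-like cluster led by Igfbp4, Tcf7 and Lef1. Without the Foxp3-rich clusters, an alternative chosen after the data were seen that left 758 and 395 cells, all 24 named genes kept their direction and 22 stayed at least 2-fold. Klrg1 and Trf fell under 2-fold, Trf to a log2 size of 0.54. Without cluster 14, chosen likewise, which left 785 and 511 cells, 22 of the 24 kept their direction and stayed at least 2-fold, while Igfbp4 and Dapl1 turned to log2 ratios of 0.20 and 0.22.

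The lists that describe regulatory, exhausted and dividing cells depended on that choice. The regulatory T cell list had a median of -0.95 (-1.08 to -0.81), with 11 of 24 members at least 2-fold lower, and 0.09 (-0.15 to 0.17) without the Foxp3-rich clusters. The exhaustion list went from -0.59 (-0.71 to -0.46) to -0.15 (-0.26 to -0.01), and the interleukin-2 and STAT5 list from -0.47 (-0.56 to -0.42) to -0.09 (-0.27 to 0.05). The proliferation list went from -0.23 (-0.26 to -0.06), at the middle of the random lists, to 0.42 (0.25 to 0.53), and was -1.05 with whole clusters. Havcr2 was 2.79-fold higher within the exhaustion list, and Rgs16, Prdm1 and Ikzf2 were at least 2-fold lower. Mki67 was found in 9.16% and 8.59% of the thinned cells, a difference of 0.569 points (-2.85 to 3.87), with 106 and 61 shallower cells left out and 12.97% and 14.02% before thinning. Without the Foxp3-rich clusters the difference was 3.58 points (0.125 to 6.75), and with whole clusters in place of the gate -4.82 points. The chemokine and homing list went from -0.39 (-0.47 to -0.25) to 0.12 (-0.14 to 0.20).

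Naive and memory genes had a median of -0.88 (-0.95 to -0.79), below all the random lists, with 9 of 22 members at least 2-fold lower, among them Tcf7, a transcription factor of naive and stem-like T cells (2.78-fold), and the lymph node homing receptor Ccr7 (2.29-fold), and with Ly6c1 and Ly6c2 higher. The median without the Foxp3-rich clusters was -1.13, and with whole clusters -0.52. Without cluster 14 it was -0.50 (-0.58 to -0.35), with 3 of 22 members at least 2-fold lower. Glycolysis genes had a median of 0.38 (0.30 to 0.46), above all the random lists, with Aldoa 1.72-fold, Eno1 1.87-fold and Gapdh 1.60-fold higher, 0.75 without the Foxp3-rich clusters and 0.26 without cluster 14. Oxidative phosphorylation genes had a median of 0.19 (0.16 to 0.235). Cytotoxic effector genes had a median of 0.05 (-0.03 to 0.16, percentile 99.8), with Ifng 2.68-fold and Nkg7 2.81-fold higher and Gzmd, Gzme and Gzmf lower, 0.20 without the Foxp3-rich clusters, 0.64 with whole clusters in place of the gate, -0.0125 with a gate at 2 UMIs and -0.06 without cluster 14, so it had no stable sign. Free RNA also held more Ifng with mSTAR1302, 1162.1 against 356.1 CPM. After thinning, Ifng was found in 36.5% of these cells against 17.9%, and in 15.15% of macrophage-like cells against 5.77%. Of 12 T helper genes, Ifng, Il12rb2, Il4 (2.18-fold) and Il13 were at least 2-fold higher and Cxcr5 lower, with a median of 0.17 (-0.03 to 0.39). Interferon-response genes had a median of -0.31 (-0.39 to -0.21, percentile 3.20), with Rsad2 (2.43-fold) and Ifit3 (2.29-fold) among 6 lower members. T cell receptor signalling genes had a median of -0.33 (-0.40 to -0.25), with Cd40lg 2.16-fold higher and Egr2 3.07-fold lower. Medians were -0.15 for heat shock and dissociation, 0.03 for apoptosis and stress, whose interval held 0 (0.23 without the Foxp3-rich clusters), and 0.16 for RNA quality (0.07). Macrophage markers had a median of -1.71, dendritic cell markers -1.18 and tumour markers -0.76.

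The fifth comparison took the CD4 cells with a Foxp3 UMI, 143 cells with mSTAR1302 and 1327 with vehicle. Of the regulatory list, 1 of 25 measured members was past 2-fold (Klrg1, 2.45-fold lower), and the median was -0.11 (-0.23 to -0.07, percentile 42.8), turning to 0.01 with median-ratio scaling. Foxp3 (ENSMUSG00000039521, plus strand of chromosome X at 7573644 to 7595245), on which the cells were selected, was at 351 against 411 CPM. The 6 largest upward were Gzma (24.1-fold), Ifitm1 (13.5-fold, 11.7 to 15.5), Ly6c2 (5.97-fold), Il12rb2 (5.21-fold), Cd40lg, the ligand of CD40 (4.91-fold, 3.605 to 6.63), and Ifitm3 (4.085-fold). Gzma was not above background here, since after thinning it was found in 10.5% of these cells and 13.6% of macrophage-like cells of the mSTAR1302 library. Ly6c2 was found in 10.5% of these cells without thinning and in 8.37% of near-empty droplets of that library, and its 41.4 CPM stood beside 376.0 CPM in free RNA. This gate did not hold like cells in both libraries either. Cluster 3 held 10.5% of it with mSTAR1302 and 1.73% with vehicle. In that cluster 3.87% of cells held a Foxp3 UMI, and Cd40lg and Ifitm3 were among its top 10 genes. Whether cells of cluster 3 carry the higher Cd40lg, Ifitm1 and Ifitm3 was not tested. The 6 largest downward were Tff1, with 2 UMIs against 307 (ratio of 13.5 toward vehicle, 3.71 to 112), Pcsk1 (6.74-fold), the macrophage marker Lyz2 (5.70-fold), Zeb2 (5.69-fold), Adam8 (4.56-fold) and Rgs16. Free RNA carried the same contrast for Lyz2, with 181.2 against 993.4 CPM beside 6.5 against 37.05 CPM in these cells. Among 5698 genes 30 were at least 2-fold higher and 80 lower, with a median of -0.13. With median-ratio scaling they were 43 and 49, or 46.7% higher in place of 27.3%. Naive and memory genes had a median of 0.35 with 19 of 22 above 0, above all the random lists, and Bcl2, which protects cells from apoptosis, was 2.32-fold higher. Exhaustion genes had a median of -0.41, T cell receptor signalling genes -0.36, glycolysis genes -0.33, heat shock genes -0.25 and proliferation genes -0.25. The interleukin-2 and STAT5 list had a median of -0.05 and a mean of 0.03, with Pim2, Bcl2 and Lta at least 2-fold higher. RNA quality genes had a median of 0.39, above all the random lists, and macrophage markers -1.52. Mki67 was found in 24.1% and 23.9% of the thinned cells, with 10 and 61 shallower cells left out, and in 30.1% and 37.9% before thinning.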

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

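The tests of reads divided between Trbv13 segments, of depth as the whole of the Foxp3 difference and of free RNA as the whole of the Trbv13 and CD8 gene differences were chosen only after the result was seen, as was the Foxp3 reading at 3000 UMIs with the gate at full depth. Gene lists stand here where the medians had opposite signs in CD8 cells and in CD4 cells without Foxp3, both intervals excluded 0 and the medians lay at least 0.5 apart, which 3 of 15 lists met. Other lists with opposite signs fell short of these limits, among them naive and memory (0.06 and -0.88, the first with an interval that held 0) and proliferation (0.11 and -0.23). With 1 library per group these differences between the populations were not tested. The median log2 ratio of the interferon list was 0.57 in CD8 cells and -0.31 in CD4 cells, 0.89 apart. That of the chemokine, homing and residence list was 0.26 and -0.39, 0.65 apart, and that of the interleukin-2 and STAT5 list was 0.08 and -0.47, 0.55 apart. The CD4 values of the last pair of lists were 0.12 and -0.09 without the Foxp3-rich clusters, where both intervals held 0, so neither list then met these limits. Without these clusters the CD4 value of the interferon list was -0.23 (-0.29 to -0.10), with an interval that excluded 0. Random lists of matched expression were also centred below 0 in CD4 cells. The main CD4 interferon value lay inside their central range of -0.33 to -0.02, at percentile 3.20. It was at percentile 7.5 without the Foxp3-rich clusters and 15.4 without the naive-like cluster. Its negative sign thus does not set the CD4 interferon list apart from matched genes, while the CD8 value lay above all the random lists. The share of Trbv13-2 and Trbv13-3, taken on sign alone, differed by 28.47 points in CD8 cells and by -0.353 points in CD4 cells, 28.82 points apart, where the CD4 interval held 0 (-6.98 to 5.88).

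The higher Trbv13-2 and Trbv13-3 share in CD8 cells of the mSTAR1302 library was weighed against free RNA, 1 expanded clone and reads divided between similar segments. Free RNA carries the same contrast and reaches every droplet of a library, yet the interval of the difference in CD4 gated cells ended at 6.95 points, under the 10 points set as the bound, which argues against free RNA as the whole of it. Subtracting free RNA left 28.65 points, a weak test since little was subtracted, and pooling Trbv13-1, Trbv13-2 and Trbv13-3 left 26.53 points, above the bound of 20. In cells with Trbv13-2 or Trbv13-3 the most frequent Trav segment, Trav16n, took 24.29% of 420 Trav UMIs (20.3 to 28.7%) and 56 Trav genes were seen, which argues against 1 clone, set at over 50%, although the bound of 25% lies inside the interval and Trav16n also led in cells with another Trbv (28.3%) and in the vehicle cells with Trbv13-2 or Trbv13-3, where it took 47.6% of 105 UMIs (37.8 to 57.6%). Expansion or recruitment of many T cells that carry these chains, which mSTAR1302 binds, may therefore be a candidate explanation, and a difference between the mice of the 2 libraries stays open.

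The lower Foxp3 share of CD4 cells was weighed against depth, free RNA and loss of cells in the filters. Thinning every cell to 1000 UMIs before gating left -19.94 points (-24.1 to -15.5), just inside the -20 points set beforehand as the mark of a depth effect. Thinning lowers Foxp3 detection in both libraries, so a smaller difference in points cannot by itself show a depth effect. The shares still differed 3.66-fold, and depth as a part of the gap stays open. Depth as the whole of it is argued against by the reading at 3000 UMIs, whose interval ended at -36.72 points. With at least 2 Foxp3 UMIs required the difference was -46.59 points, and under the looser filters it was -49.81 points or below, which argues against free RNA and against lost cells. A lower share of regulatory cells after mSTAR1302 stays open as a hypothesis, untested across mice.

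The 24 genes named by size in CD8 cells had a median size of 2.40 on the log2 scale, and 2.41 after free RNA was subtracted, a weak test since little was subtracted. Macrophage markers allow free RNA at most 7.86% and 4.23% of the UMIs of CD8 gated cells, while each of the 24 genes would need at least 15.07% from it, which argues against free RNA as the whole of the difference. Without CD8 gated cells that held a Foxp3 UMI the median was 2.30 and all 24 genes kept their direction. This argues against cells with a detected Foxp3 UMI as the whole source. Regulatory cells without such a UMI stay in the gate, where the regulatory list still had a median of -0.78. Cluster 2, with a Foxp3 UMI in 83.6% of cells, held 5.02% of the vehicle gate and 0.369% of the mSTAR1302 gate. Regulatory cells, or doublets with them, as a part of the difference in the lower genes thus stay open. Whether cells with Trbv13-2 or Trbv13-3 carry the pattern stayed open, since the median was 2.84 in such cells and 1.66 in cells with another Trbv, a ratio of 0.583 between the bounds of 0.5 and 0.8 set beforehand, with 24 genes in the same direction in the latter. Cells with a Trbv12-2 UMI counted among those with another Trbv, unless they also held Trbv13-2 or Trbv13-3. These tests could not separate treatment from a difference between the mice.

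Barcodes of at least 500 and under 1000 UMIs were left out of the comparisons, and 4458 of them were found in the mSTAR1302 library and 2096 in the vehicle library, or 48.7 and 27.5 per 100 kept cells. Over 10% mitochondrial UMIs were found in 64.0% and 67.1% of these barcodes, Cd8a or Cd8b1 in 29.6% and 15.7%, and Foxp3 in 1.503% and 7.68%.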

How the results depend on the processing

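The alternatives that remove the highest doublet scores, take whole clusters, drop Foxp3 cells from the CD8 gate, thin Foxp3 to 3000 UMIs with the gate at full depth, and leave out the Foxp3-rich clusters or the naive-like cluster were chosen only after the result was seen, and all others before the data were examined. No paired analysis was possible because each group holds 1 library and no test was made. Of 315 values of 21 results under an alternative, 234 lay within the main interval or, for counts, within 1.5 times the main count, 77 lay outside those limits, and 4 values called apart from 0 changed sign. The Mki67 difference in CD8 cells (0.266 to 2.06 points) and the Trbv13-2 and Trbv13-3 differences in CD8 cells (27.98 to 30.14 points) and in all CD4 cells (1.32 to 2.62 points) did not move past their intervals under any alternative run, but the interval of the first, which held 0, excluded it without Foxp3 cells (2.06 points) and with whole clusters (1.61). No result did so with free RNA subtracted, other UMI and gene minimums, or a Trbv minimum. The same held for both doublet settings, which say nothing about stability against doublets, since keeping them returns 3 cells and the scores come from a caller that did not work. The intervals are narrow where UMIs are many, so small shifts pass them. The Foxp3 and CD8 differences both shrank on thinning. Thinning lowers detection in both libraries, so the shrinkage cannot by itself show how far depth limits these comparisons. With Foxp3 thinned to 3000 UMIs and the gate at full depth, the Foxp3 shares still differed 4.39-fold. Unless the setting itself shows it, the cause was not tested.

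For the shares, the CD8 difference was 17.48 points with cells thinned to 1000 UMIs and 26.87 with a gate at 2 UMIs. The Foxp3 difference was -19.94 points thinned to 1000 UMIs, -40.08 with Foxp3 thinned to 3000, -57.74 with a gate at 2 UMIs, -49.81 on all kept cells and -50.5 with up to 20% mitochondrial UMIs. The Mki67 difference in CD4 cells was -3.70 points thinned to 1000 UMIs and -4.82 with whole clusters.

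For list medians in CD8 cells, gating all kept cells gave -0.0798 for cytotoxic, -0.56 for exhaustion, 0.12 for interleukin-2, 0.18 for naive and memory and a changed sign of -0.0467 for proliferation genes. Median-ratio scaling gave -0.10, -0.58, 0.19, 0.17 and 0.23 in that order, shifts that follow from the moved centre. Weighting cells equally gave -0.33, -0.78, a changed sign of -0.016 for interleukin-2, and 0.20 for proliferation. A gate at 2 UMIs gave -0.63 for exhaustion, 0.13 for interleukin-2, 0.17 for naive and memory and 0.22 for proliferation. Without Foxp3 cells these were -0.61, 0.13, 0.18 and 0.29. A total without receptor, mitochondrial and ribosomal genes gave -0.16 for cytotoxic, 0.13 for interleukin-2 and 0.16 for proliferation. Whole clusters gave -0.38 for cytotoxic, 0.17 for naive and memory and 0.26 for proliferation. At 10 CPM the naive and memory median was 0.29, at a pseudocount of 5 CPM the exhaustion median was -0.58, and at 5% mitochondrial UMIs the proliferation median was 0.14.

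In CD4 cells without Foxp3, leaving out the Foxp3-rich clusters gave 0.20 for cytotoxic, -0.15 for exhaustion, -0.0914 for interleukin-2, -1.13 for naive and memory and a changed sign of 0.42 for proliferation genes. Without the naive-like cluster they were -0.0648 for cytotoxic, -0.57 for interleukin-2, -0.50 for naive and memory and -0.27 for proliferation. Whole clusters gave 0.64, -0.72, -0.61, -0.52 and -1.05 for all 5 lists in the first order. Gating all kept cells gave 0.21 for cytotoxic, -0.32 for interleukin-2 and -0.61 for naive and memory. Median-ratio scaling gave 0.21 for cytotoxic, -0.44 for exhaustion, -0.31 for interleukin-2 and -0.72 for naive and memory. Weighting cells equally gave 0.22 for cytotoxic and -0.71 for naive and memory, a gate at 2 UMIs gave -1.003 for naive and memory, and the smaller total gave -0.40 for interleukin-2. Mitochondrial limits of 5% and 20% gave 0.20 for cytotoxic and -0.26 for proliferation. In CD4 cells with Foxp3 the regulatory median changed sign to 0.0131 with median-ratio scaling, and was -0.0278 with the smaller total and -0.0681 at 5% mitochondrial UMIs.

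The counts of genes at least 2-fold apart moved with the CPM minimum, which sets how many genes are counted. Without a minimum 118 were higher and 545 lower in CD8 cells, and 113 and 893 in CD4 cells without Foxp3. At 50 CPM they were 33 and 82, and 29 and 73. On all kept cells 293 were lower in CD8 cells and 429 in CD4 cells, and with median-ratio scaling 129 were lower in CD4 cells.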

Other observations

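The comparison of CD8 cells by receptor within a library was chosen only after the result was seen, while the test of Trbv12-2 was set beforehand. Within the mSTAR1302 library, 801 CD8 gated cells with a Trbv13-2 or Trbv13-3 UMI were set against 794 with another Trbv UMI, and in the vehicle library 100 against 497. The comparison cells included those with Trbv12-2 but neither Trbv13-2 nor Trbv13-3. Trbv12-2 was found in 356 cells of the mSTAR1302 library, 81 of them in the Trbv13-2 and Trbv13-3 group. With vehicle it was found in 66 cells, 14 of them in that group. If Trbv12-2 marks cells that carry Trbv13-2 or Trbv13-3, a possibility taken up below, the comparison cells are mixed, and more so with mSTAR1302. The genes named here were picked after their values were seen. In the mSTAR1302 library the Trbv13-2 and Trbv13-3 cells held more of the granzymes Gzma (2.375-fold, 2.30 to 2.45) and Gzmb (1.38-fold), of Klf3 (2.31-fold) and of Lef1 (1.83-fold), a transcription factor of naive and memory T cells. The vehicle ratios were 0.744 for Gzma, 1.02 for Gzmb and 0.842 for Klf3. Mki67 was 1.67-fold higher with mSTAR1302 and 1.33-fold with vehicle.

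The same Trbv13-2 and Trbv13-3 cells held fewer transcripts of the effector cytokine Ifng, at 584.9 against 2306 CPM, 3.94-fold lower, where the vehicle cells had it 1.72-fold higher. The inhibitory receptors Pdcd1 (3.255-fold) and Lag3 (2.625-fold), the transcription factor Tox (3.09-fold), the chemokine Xcl1 (2.54-fold) and the pore-forming protein Prf1 (2.29-fold) were lower too, against vehicle values of 1.22-fold lower for Pdcd1 and 1.02-fold for Lag3. By list, median log2 ratios were 0.72 for interferon response genes (0.41 in the vehicle library), 0.40 for proliferation genes (0.39), -0.49 for exhaustion genes (-0.03), -0.31 for cytotoxic genes (0.03), -0.34 for glycolysis genes (-0.02) and -0.41 for regulatory genes (0.10). In the mSTAR1302 library cluster 0 held 59.2% of the Trbv13-2 and Trbv13-3 cells and 26.6% of the others. Cluster 5, with Ifng, Xcl1 and Il13 among its top 10 genes, held 2.87% and 16.5%. Cluster 1, with Slc17a6 and Pdcd1 among its top 10, held 7.49% and 25.6%. How far this makeup sets the gene ratios was not tested. The intervals cover counting error only, and the cells come from 1 library each.

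Trbv12-2 was also at a higher share in CD8 cells of the mSTAR1302 library, and a candidate explanation is that its UMIs lie in cells that carry Trbv13-2 or Trbv13-3. Of 356 cells with a Trbv12-2 UMI in that library 22.8% also held a Trbv13-2 or Trbv13-3 UMI, against 7.49% of 561 cells with another Trbv, a ratio of 3.04 where at least 2 had been set as the mark of this explanation. In the vehicle library the shares were 21.2% of 66 and 3.05% of 459. The overlap covers a minority of the Trbv12-2 cells, and why the transcripts occur together was not tested.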
